A study of Homo sapiens with 6 samples.

How the data were processed

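NRF2 occupancy was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in HMC3, an established human microglial cell line. The 4 immunoprecipitated libraries were 2 vehicle libraries and 2 libraries from cells given CDDO-Im, a synthetic triterpenoid activator of NRF2, at 30 nM for 4 h. The treatment text in the labels is the same for every sample, so the groups were taken from the sample titles. The 2 input samples have no peak list and were not analysed here.

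Per the submitters' processing notes, bcl2fastq 2.15.0, BWA 0.7.17 and MACS2 2.2.7.1 were used, with hg38 and GRCm38 named as builds. Control, threshold and duplicate handling are not given in the sources used here. Chromosome names and positions in the lists fit hg38, and all coordinates are given on it. The peak names carry 1 library each, so peaks were listed per library and not on pooled samples. The deposited lists give a fold enrichment (ratio) per peak, which is the authors' value and was used only to describe, rank or filter peaks within a list. They also give the −log10 p and −log10 q of each peak as deposited, and a deposited score that is 10 times the −log10 q, cut to a whole number. The lowest −log10 q in the lists was between 1.31 and 1.33.

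For a comparison across libraries, the tags at each summit were recovered from the deposited fold enrichment and −log10 p, taking fold as tags plus 1 over background plus 1 and p as the Poisson tail above the tags. Whole tags matched for 100% of peaks in each library, with a tolerance of 0.001 plus 0.0002 of the value, and between 97.7% and 99.4% of peaks had a single match. When p was permuted over peaks, between 1.6% and 2.8% matched. The lowest recovered background of a library was taken as its genome-wide background and as a measure of depth, since library totals are not in the lists. It was 0.316 and 0.315 tags for vehicle 1 and 2, and 0.332 and 0.367 tags for CDDO-Im 1 and 2. This background also depends on the fragment length used in peak calling, which is not given in the sources used here. Tags were divided by it before libraries were compared. The shortest listed peaks were 201, 169, 206 and 177 bp in the same order, and the background over this width was used as another measure of depth. By that measure 202 of the 230 regions of all 4 libraries outside dense megabases were higher in both CDDO-Im libraries.

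Peaks on chromosomes 1 to 22 and X were joined into regions where they overlapped by at least 1 bp, and a library held a region when it listed a peak there. Chance overlap came from 1000 random placements on the same chromosome (one-sided permutation test). Class counts were compared with those from permuting list membership over the regions. Peak numbers were compared by an exact two-sided permutation test on log2 numbers, which with 2 libraries against 2 cannot give a p under 0.333. Nothing in the labels says that replicates came from separate cultures, so the spread between these libraries may be technical. Only tests that permute libraries use this spread, and tests over genes, regions or random placements do not measure it.

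Genes were the 19974 protein-coding genes of the RefSeq table on GRCh38.p14. This table gives no strand and no exons, so distances were taken to either end of a gene in place of the transcription start site, and regions are described as inside or outside a gene by their summit. A peak counted as near a gene end within 1000 bp. For gene lists, a gene counted when a region summit lay within 10 kb of either end, and lists were compared with all other protein-coding genes by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over 16 lists. The first 7 lists together made the NRF2 target list of 94 genes, of which 93 were matched. Of the 213 genes in all lists, 210 were matched. Intervals of shares are exact 95% binomial intervals and cover counting error only.

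Groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes 10 known NRF2 targets and pathway genes (within 10 kb, or 50 kb where no region lay closer), the 15 regions highest by the lower CDDO-Im fold enrichment among regions held by both CDDO-Im libraries and neither vehicle library, the 10 highest by lowest fold enrichment among regions of all 4 libraries, the 5 highest among regions of both vehicle libraries and neither CDDO-Im library, and up to 4 members of each list. The text names part of these in full, and 1 of them is not reported here. After the data were seen, megabases holding more than 20 joined regions were set apart as dense megabases, and results are given with and without them. Motif searches and the soft-masked repeat filter need a genome sequence and were not run.

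The recovery of tags, the region classes, the overlap test and the list test were tested on simulated data. The thinning of tags and the gene-end shares were not tested in this way. Tags were recovered for 1996 of 2000 simulated peaks, all 1200 simulated regions of both CDDO-Im and neither vehicle library were found, and 13 of 500 random lists of 93 genes gave a p under 0.05. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives tried were stricter peak thresholds, other overlap rules, lists of equal length, all sequence names, other distances and backgrounds for genes, each library left out, and a replicate block.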

Results

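NRF2, the transcription factor that drives antioxidant and detoxification genes, was mapped by ChIP-seq in HMC3 microglial cells given vehicle or CDDO-Im (30 nM, 4 h), with 2 libraries per group. The deposited lists held 4227 and 7448 peaks for vehicle 1 and 2, and 4024 and 12433 peaks for CDDO-Im 1 and 2. On chromosomes 1 to 22 and X these were 4098, 7308, 3882 and 12244 peaks. The genome-wide background, a measure of depth, lay between 0.315 and 0.367 tags per library. Median tags at the summit of a peak were 7, 8, 10 and 9 in the same order, so most peaks rested on few tags.

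The first question was how far NRF2 occupancy across the genome differed between vehicle and CDDO-Im. Outside dense megabases, the CDDO-Im libraries listed 3249 and 4795 peaks and the vehicle libraries 1216 and 1276, a ratio of group means on the log2 scale of 1.66, or 3.17-fold. Over all peaks the difference was 0.33 on the log2 scale and smaller than the spread between replicates. It was 1.36 (2.56-fold) for peaks with a −log10 q of at least 5, and 2.38 (5.22-fold) at one of at least 10, where the vehicle libraries listed 203 and 701 peaks and the CDDO-Im libraries 1299 and 2986. Dense megabases were 77 megabases in 26 blocks on 23 chromosomes with more than 20 joined regions each, of which 64 held no protein-coding gene. Other megabases with a region held a median of 3, and 8.11% of them held no such gene. No repeat filter was run, so NRF2 occupancy in dense megabases cannot be told from signal of repeats. Dense megabases held 70.3% of the peaks of vehicle 1, 82.5% of vehicle 2, 16.3% of CDDO-Im 1 and 60.8% of CDDO-Im 2. The exact permutation p was 1 over all peaks, 0.667 at a −log10 q of at least 5, and 0.333 at one of at least 10 and outside dense megabases (two-sided, n = 2 and 2), the smallest this design allows. Without vehicle 1 the difference over all peaks was -0.08, and without CDDO-Im 2 it was -0.50, on the log2 scale.

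**Figure D1:**
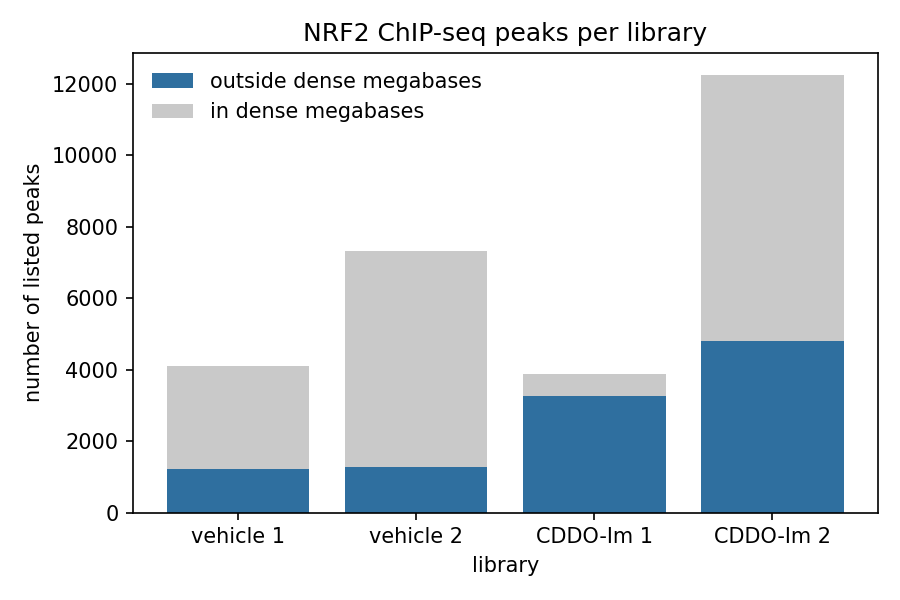
Number of listed peaks on chromosomes 1 to 22 and X in each library, with peaks in dense megabases in grey and all others in blue. Blue bars reach 1216 and 1276 in the vehicle libraries, and 3249 and 4795 in the CDDO-Im libraries.

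Outside dense megabases, NRF2 regions were shared more between the CDDO-Im libraries than between the vehicle libraries. There, 65.1% of the peaks of CDDO-Im 1 overlapped a peak of CDDO-Im 2, against 20.1% of the peaks of vehicle 1 with vehicle 2. Across groups, 31.6% and 32.8% of vehicle 1 peaks and 44.4% and 46.9% of vehicle 2 peaks overlapped the longer lists of CDDO-Im 1 and 2. Taken over the longer list of each pair, the shares were 44.2% within CDDO-Im, 19.5% within vehicle, and 11.8%, 8.4%, 17.3% and 12.5% across groups. With dense megabases included, the shares of the shorter list were 63.6% within CDDO-Im and 35.4% within vehicle, but those of the longer list were 20.4% and 20.2%. Vehicle 2 and CDDO-Im 2 then shared 47.9% of the shorter and 28.3% of the longer list. Every pair lay above chance, which was at most 0.285% on average (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). A difference in overlap between groups was not tested.

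The next comparison asked which regions were gained or lost with CDDO-Im. Outside dense megabases, 1428 regions were held by both CDDO-Im libraries and neither vehicle library, and 4 by both vehicle libraries and neither CDDO-Im library. A further 230 regions were held by all 4 libraries and 458 by both CDDO-Im and 1 vehicle library. With dense megabases included, the counts were 1475 gained, 239 lost and 433 in all 4, and 235 of the 239 lost regions lay in dense megabases. Of the other pairs of libraries, vehicle 2 with CDDO-Im 2 held the most regions that the remaining libraries lacked outside dense megabases, 42. With dense megabases included, that pair alone held 1841 regions, more than the 1475 of the CDDO-Im pair, and 1799 of the 1841 lay in dense megabases. The CDDO-Im lists were longer. Among the 1216 top peaks of each library outside dense megabases, 359 regions were held by both CDDO-Im and neither vehicle library, and 22 the reverse. Any other pair held at most 30. This cut keeps all of vehicle 1 but only the strongest peaks of the CDDO-Im libraries, which listed 3249 and 4795. It thus does not separate the gain from list length, and a region below the cut can still be listed. Permuting list membership over the listed regions gave 1457.1 gained, 41.3 lost and 59.6 in all 4 libraries, but it takes only regions that some library lists and is no measure of chance overlap across the genome. At a −log10 q of at least 10, gained regions outside dense megabases were 906 and those of all 4 libraries 57, and at one of at least 5 the latter were 150. Leaving out a library, outside dense megabases, gave 1570 gained regions without vehicle 1, 1744 without vehicle 2, 4033 without CDDO-Im 1 and 2539 without CDDO-Im 2. Lost regions were then 662, 806, 8 and 10, and regions in all remaining libraries 546, 372, 236 and 234.

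Absence from a vehicle list is not absence of NRF2, because a weak peak can go unlisted. In the 1428 gained regions the median was 11 tags in CDDO-Im 1 and 16 in CDDO-Im 2. The median listed peak of the vehicle libraries outside dense megabases had 6 and 7 tags. Had the vehicle libraries held that many tags unlisted in each gained region, 595 of the 1428 (41.7%) would have passed a test for more CDDO-Im tags (binomial test on summed tags, one-sided, adjusted threshold of 0.05). The median of the summed CDDO-Im tags was 27 against the assumed 13, so regions that did not pass could still have had more. That setting is a high one, since vehicle peaks at the genome-wide background were listed from 4 tags. Sites with 6 and 7 tags at that background would mostly have been listed. The share thus does not tell how many gained regions NRF2 already occupied under vehicle. The binomial test covers counting error only, and the choice of regions listed in both CDDO-Im libraries raises its share.

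Most regions listed in all 4 libraries outside dense megabases had more tags with CDDO-Im. In 200 of the 230 regions of all 4 libraries outside dense megabases (87.0%), both CDDO-Im libraries had more tags over background than both vehicle libraries, where chance gives 16.7%. The median ratio of CDDO-Im to vehicle was 3.26, with quartiles of 2.46 and 3.85. Both CDDO-Im libraries were lower in 9 regions. In the 203 regions of all 4 libraries inside dense megabases the median ratio was 0.899, with 7 regions higher and 56 (27.6%) lower in both CDDO-Im libraries. Of the 458 regions held by both CDDO-Im and 1 vehicle library, 424 had more tags over background in both CDDO-Im libraries than in that vehicle library. Choosing regions that 1 vehicle library did not list favours that outcome, so it adds little to the regions of all 4 libraries. Regions are not replicates, so these shares carry no p-value over libraries.

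HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, had the strongest region of all 4 libraries by lowest fold enrichment. This region (chromosome 22, 35371769 to 35372408) lay outside the gene, 8994 bp from its nearer end, and held 36 and 46 tags in the vehicle libraries against 114 and 188 in the CDDO-Im libraries. Over background these were 114 and 146 against 344 and 512. Another region 3974 bp from HMOX1 (35376864 to 35377373) held 22 and 22 against 53 and 109 tags. NQO1, a quinone reductase, had a region outside the gene 456 bp from its end (chromosome 16, 69726731 to 69727237) with 12 and 20 tags under vehicle and 68 and 97 with CDDO-Im. The ferritin heavy chain gene FTH1 had a region 4415 bp away (chromosome 11, 61971835 to 61972288) with 12 and 17 against 49 and 104 tags. SQSTM1, an autophagy receptor, had none within 10 kb of its ends, but a region inside the gene (chromosome 5, 179820245 to 179820871) held 9 and 6 against 23 and 53 tags. In each of these 5 regions both CDDO-Im libraries lay above both vehicle libraries, with an exact permutation p of 0.333 at best for n = 2 and 2.

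**Figure D2:**
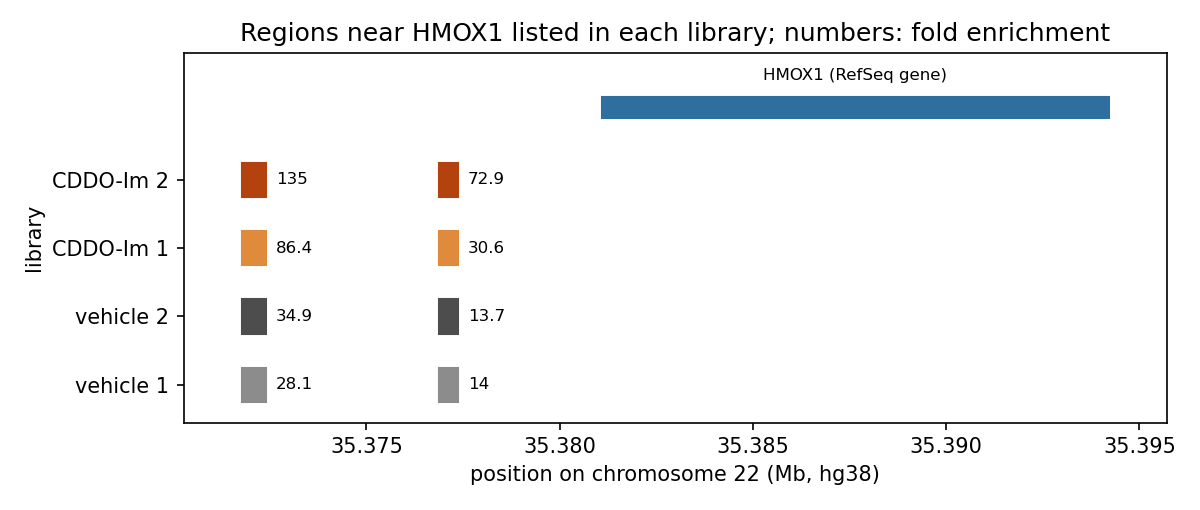
Map of chromosome 22 around HMOX1 (position in Mb, hg38), with the gene in blue and the extent of the 2 joined regions drawn for each library that lists a peak there. Numbers are the authors' fold enrichment per library, and the region 8994 bp from the gene has 28.1 and 34.9 under vehicle and 86.4 and 135 with CDDO-Im.

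Other known NRF2 targets were listed mainly with CDDO-Im. GCLM and GCLC, the subunits of the enzyme that makes the first step of glutathione synthesis, had regions in both CDDO-Im libraries (20 and 28 tags at GCLM, 20 and 18 at GCLC) and in vehicle 2 alone of the vehicle libraries (11 and 9 tags). The GCLM region (chromosome 1, 93909268 to 93909669) spanned an end of the gene, with its summit 46 bp outside, and the GCLC region (chromosome 6, 53548076 to 53548402) lay 3140 bp outside. TXNRD1, thioredoxin reductase 1, had a region inside the gene (chromosome 12, 104219368 to 104219681) listed in both CDDO-Im libraries, with 16 and 22 tags, and in neither vehicle library. SLC7A11, the cystine transporter, had only regions listed in 1 library each, with 7 tags in CDDO-Im 1 and 13 in CDDO-Im 2 at different places. MAFG, a small MAF partner of NRF2, had 3 regions, all listed in CDDO-Im 2 alone, with 15 to 21 tags. No library listed a peak within 50 kb of an end of SRXN1 or of NFE2L2, the gene of NRF2 itself. At these depths that does not show that NRF2 was absent there.

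**Figure D3:**
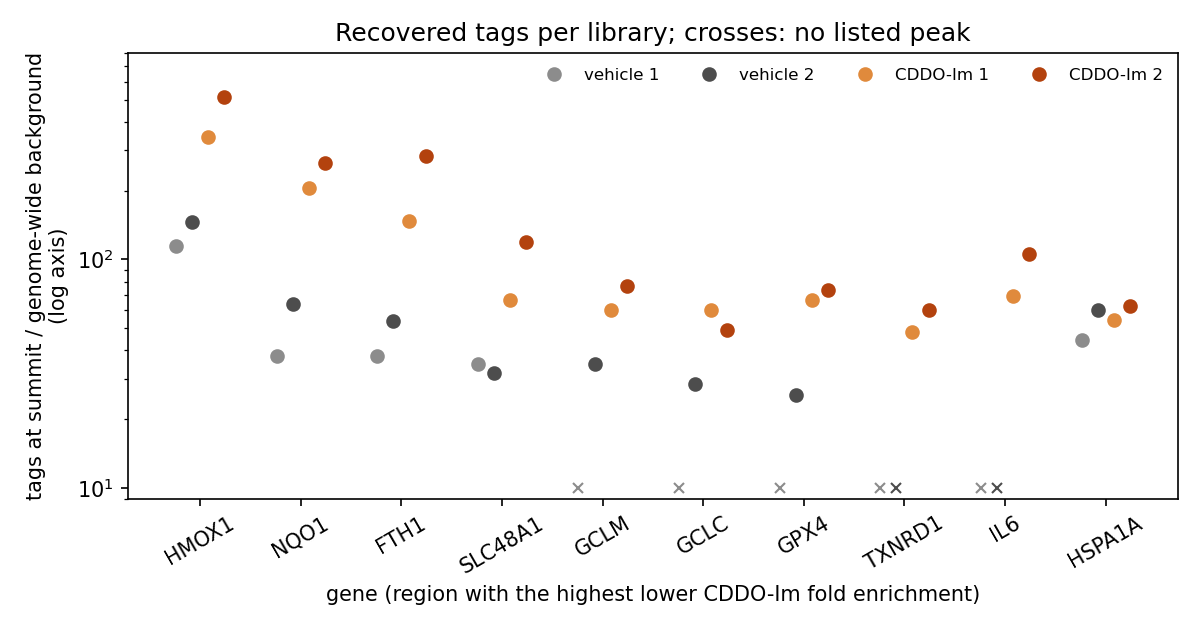
Recovered tags at the summit over the genome-wide background (log axis, no unit) for 1 region each near 10 genes, as a point per library. Crosses at the foot mark libraries that list no peak and carry no value. At HMOX1 the vehicle libraries lie at 114 and 146 and the CDDO-Im libraries at 344 and 512.

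As a group, NRF2 target genes lay near NRF2 regions more often than other genes in both conditions. Of the 93 target genes, 13 (14.0%, exact interval 7.66% to 22.7%) had a region of both CDDO-Im libraries within 10 kb, against 480 of 19881 other genes (2.41%), an odds ratio of 6.57 (Fisher's exact p = 4.63e-07). Regions of both vehicle libraries lay near 4 target genes (FTH1, HMOX1, NQO1 and SLC48A1), an odds ratio of 11.0 (Fisher's exact p = 0.000669). Regions held by both CDDO-Im and neither vehicle library lay near 5 (EPHX1, FECH, FTL, ME1 and TXNRD1), an odds ratio of 3.84 (Fisher's exact p = 0.0123). In the target list 9 genes had a region of both CDDO-Im libraries but not of both vehicle libraries, and 0 the reverse. Over all protein-coding genes these numbers were 408 and 0, so that direction was not particular to the target list. Against genes with a peak within 50 kb, the odds ratios were 3.17 for CDDO-Im and 5.18 for vehicle regions. Against all other genes, the vehicle odds ratio fell from 11.0 to 6.16 without vehicle 1 (8 genes) and 3.85 without vehicle 2 (5 genes), where a single list stands for the group. The CDDO-Im count was 28 of 93 genes without CDDO-Im 1 (odds ratio 7.49) and 18 without CDDO-Im 2 (6.60). With regions anywhere in the gene or within 10 kb of it, 20 target genes had a CDDO-Im region (4.52) and 8 a vehicle region (12.1). Within 1 kb of a gene end the odds ratios were 15.4 for CDDO-Im (4 genes) and 30.9 for vehicle (1 gene), and within 50 kb 4.02 (29 genes) and 7.27 (10 genes), each with a Fisher's exact p under the threshold of 0.05.

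Among the lists, heme and iron genes stood out. Of 10 genes, 6 (ABCB6, FECH, FTH1, FTL, HMOX1 and SLC48A1) had a region of both CDDO-Im libraries, an odds ratio of 60.0 (Fisher's exact test, adjusted p = 6.78e-07), and 3 had one of both vehicle libraries (adjusted p = 0.00014). FECH, the last enzyme of heme synthesis, had a region 295 bp outside the gene (chromosome 18, 57586829 to 57587158) with 18 and 30 tags in the CDDO-Im libraries. FTL, the ferritin light chain, had 8 and 33 tags, and SLC48A1, a heme transporter, had 11 and 10 tags under vehicle against 22 and 44. Glutathione genes had 3 of 16 (GCLC, GCLM and GPX4; Fisher's exact test, adjusted p = 0.0527). Detoxification genes had 2 of 19 (EPHX1 and NQO1; Fisher's exact test, adjusted p = 0.316), and thioredoxin (TXNRD1, 1 of 12) and pentose phosphate genes (ME1, 1 of 10) each had an adjusted p of 0.556.

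The remaining lists did not pass the test for CDDO-Im regions. Autophagy and proteasome genes, NRF2 pathway regulators, AP-1 genes, the unfolded protein response and markers of microglia, mesenchymal cells and astrocytes or oligodendrocytes had 0 genes each with a region of both CDDO-Im libraries within 10 kb of a gene end. Regions inside a gene but farther from its ends are not counted. Examples are those in SQSTM1 of the autophagy list (14155 bp from an end) and SYT1 of the neuron list (219403 bp). The inflammatory list had 1 of 15: IL6, an inflammatory cytokine, with a region 288 bp outside the gene (chromosome 7, 22726752 to 22727101), 23 and 39 tags with CDDO-Im and no vehicle peak (Fisher's exact test, adjusted p of the list 0.556). Neuron markers had 1 of 11, SNAP25, and highly transcribed genes 1 of 14, EEF1A1, both with an adjusted p of 0.556. Heat shock genes had 2 of 10, HSPA1A and HSPA1B, with an adjusted p of 0.128 for CDDO-Im regions and 0.0063 for vehicle regions (Fisher's exact test). These 2 genes are near-identical neighbouring copies, so their tags are uncertain and they are not independent members.

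**Figure D4:**
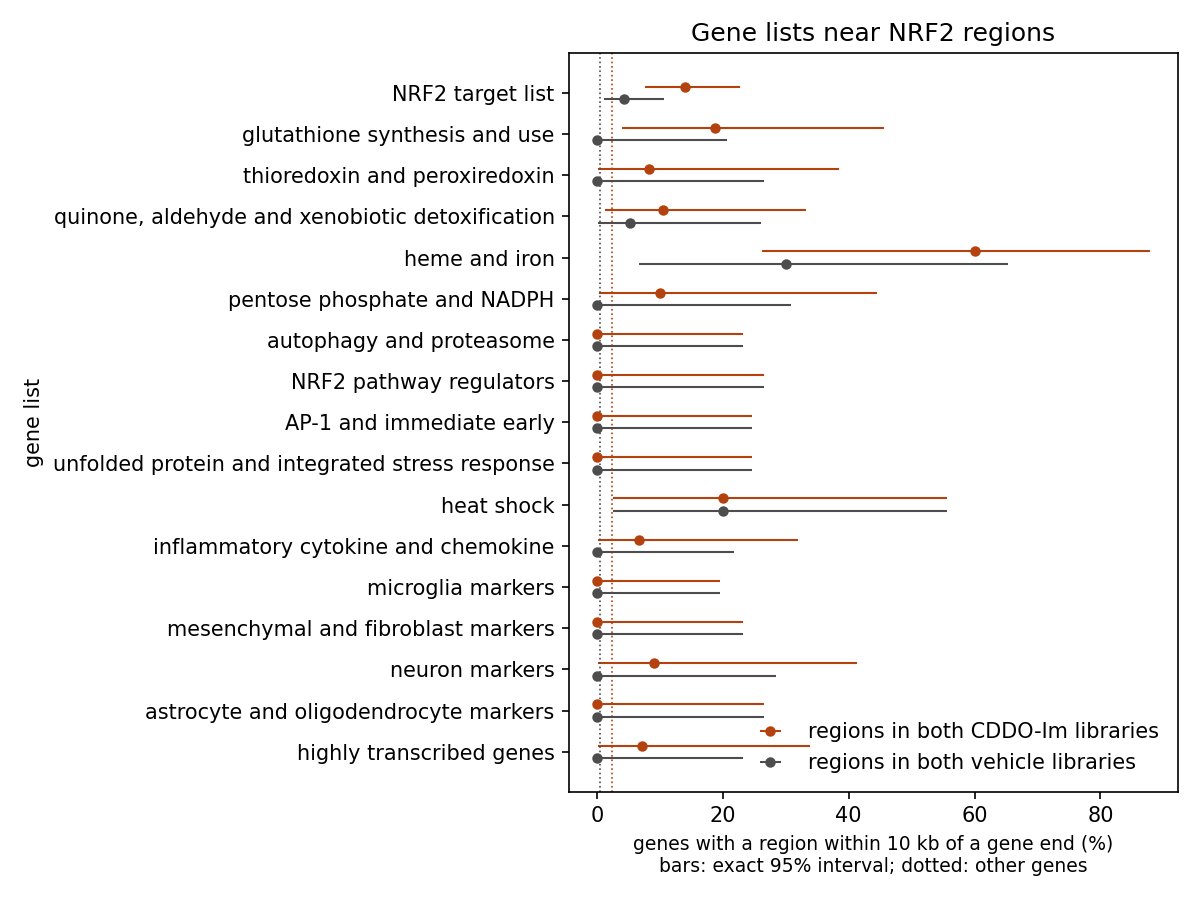
Percent of genes in each list with a region of both CDDO-Im libraries (orange) or both vehicle libraries (grey) within 10 kb of a gene end, with exact 95% binomial intervals and dotted lines for other protein-coding genes. Heme and iron genes lie highest, at 60% and 30%.

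The strongest gained regions, ranked by the lower fold enrichment of the CDDO-Im libraries, lay mostly away from gene ends. The first was inside SYT1, a synaptic vesicle calcium sensor (chromosome 12, 79083119 to 79083568), with 36 and 45 tags. Regions inside ANAPC5 (38 and 43 tags), SH3TC1 (32 and 57), RPH3A (31 and 36), NUP93 (31 and 48), SCN9A (30 and 37), TBXAS1 (35 and 72) and SOS1 (26 and 41) were also among the first 15. Others lay outside the nearest gene: MRPL3 at 8453 bp, GSTM5 at 1205 bp, LRRC8D at 1894 bp and CTTNBP2 at 124595 bp. GSTM5 encodes a glutathione transferase. Among regions of all 4 libraries, those nearest to CYYR1, PLEKHS1, EPS8L3, MAGI2 and CDH6 were among the 10 highest, and the CYYR1 region (chromosome 21, 26405641 to 26406168) held 34 and 46 tags under vehicle against 122 and 160. The region inside NDUFS7, a subunit of mitochondrial complex I, held 33 and 30 against 34 and 32 tags. The 5 highest regions of both vehicle and neither CDDO-Im library all lay in dense megabases, at least 794618 bp from a gene end, with 8 to 19 tags.

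NRF2 regions were not concentrated at gene ends. Outside dense megabases, 2.55% and 2.27% of vehicle peaks and 2.55% and 2.52% of CDDO-Im peaks lay within 1000 bp of an end of a protein-coding gene, where random placement gave 2.38% to 2.47% (permutation p between 0.53 and 0.84, two-sided). Between 42.2% and 43.5% of peaks lay inside genes farther from an end. Placement outside dense megabases gave 41.8% for both CDDO-Im libraries, against 43.4% (permutation p = 0.0689) and 43.5% (permutation p = 0.019) observed, and 42.0% and 41.9% for the vehicle libraries (permutation p = 0.806 and 0.914, two-sided). Placement over whole chromosomes gave 40.8% and 40.7% for CDDO-Im (permutation p = 0.001, the smallest that 1000 placements can give). Gained regions were near a gene end in 2.66% and regions of all 4 libraries in 3.91% (Fisher's exact p = 0.284, adjusted p = 0.284). With dense megabases included, the shares were 0.756%, 0.397%, 2.14% and 0.988%, below chance in vehicle 1, vehicle 2 and CDDO-Im 2.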

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

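Peaks on sequences other than chromosomes 1 to 22 and X, which the comparisons do not use, numbered 142 in CDDO-Im 1 and 189 in CDDO-Im 2, above the 129 and 140 of the vehicle libraries. As shares of the lists these were 3.53% and 1.52% for CDDO-Im and 3.05% and 1.88% for vehicle, so CDDO-Im 2 had the lowest share. Both libraries numbered 2 lay below both numbered 1 in this share. With 2 libraries per group these differences were not tested, and no explanation for them was weighed.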

How the results depend on the processing

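Leaving out dense megabases was chosen after seeing the data. The peak number with a replicate block was 0.33 on the log2 scale (exact sign-flip p = 1), equal to the value without it. The shared numbers were not taken as pairs. The deviations of same-numbered libraries had r of -0.037 over 230 regions outside dense megabases and 0.255 over all 433. These values do not exclude a batch shared by same-numbered libraries. Both libraries numbered 2 listed more peaks than both numbered 1, in total and in dense megabases. They also had a higher background over the shortest peak width and a lower share of peaks on other sequences. Peak numbers outside dense megabases split by treatment instead. Leaving out each library moved the peak number between -0.50 and 1.16, gained regions between 1639 and 8192, lost regions between 260 and 3741, and regions in all libraries between 452 and 1181, since 1 list then stands for its group. At a −log10 q of at least 5, lost regions were 26 and those of all 4 libraries 245. At a −log10 q of at least 10, gained regions were 912, lost regions 5 and those of all 4 libraries 120. At a fold enrichment of at least 5, lost regions were 135 and those of all 4 libraries 244. Outside dense megabases, with no threshold added, lost regions were 4 and those of all 4 libraries 230. Stricter thresholds keep fewer peaks by construction. The share of peaks near gene ends moved to the other side of chance outside dense megabases in vehicle 1 (2.55%), CDDO-Im 1 (2.55%) and CDDO-Im 2 (2.52%), and in CDDO-Im 1 at a −log10 q of at least 5 (2.61%), all without passing the test. In vehicle 2 outside dense megabases it no longer passed (2.27%), and in CDDO-Im 1 within 2500 bp it passed below chance (4.79%). The cause was not tested. Of 83 alternatives, 59 kept direction and side of the threshold or stayed within 1.5 times the count, among them each one for replicate overlap and the NRF2 target list. Not run for lack of a genome sequence were all motif results and the filter on regions over 80% soft-masked. Few tags per peak limit what the lists can show.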

Other observations

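A set of regions held by all 4 libraries outside dense megabases was not higher in both CDDO-Im libraries, and was singled out after its values were seen. Of these 30 regions, 18 lay over 50 kb from a gene end, and 22 had a fold enrichment under 6 in every library. These 22 held 39 to 341 tags per library, so their local background was high. No repeat filter was run, so NRF2 occupancy in these 22 regions cannot be told from signal of repeats. The other 8 lay at HSPA1A, HSPA1B (2 regions), HSPA2, NDUFS7, PARP2, PWP1 and TMEM131L. The region inside HSPA2, a testis-enriched member of the HSP70 family, held 15 and 19 tags under vehicle and 20 and 18 with CDDO-Im, and that at TMEM131L 15 and 17 against 16 and 14. Of the 30 regions, 5 lay within 1000 bp of a gene end, against 4 of the 200 that were higher (Fisher's exact p = 0.00237), and 3 of these 5 lay in the near-identical copies HSPA1A and HSPA1B. Another HSPA1A region was among the 4, with 12 and 10 against 17 and 17 tags. Without these copies the counts were 2 of 27 and 3 of 199 (Fisher's exact p = 0.11).

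For the patterns below, the tests of depth and treatment on dense megabases, the comparisons of pairs of libraries, the stricter thinning threshold and the depth measure that allows for peak width were chosen after the results were seen. Dense megabases held most peaks of 3 libraries and few of CDDO-Im 1. Lower depth as the whole cause is argued against, since the background of CDDO-Im 1 was 0.332 tags and the lowest of the others 0.315. Over the shortest peak width it was 1.61 tags per kb, against 1.57 in vehicle 1, which had 2882 peaks in dense megabases. By that measure vehicle 2 and CDDO-Im 2, with the most such peaks, were deeper (1.86 and 2.08), so a part for depth stays open. Since these 2 libraries share a replicate number, a batch of same-numbered libraries also stays open and was not tested. CDDO-Im treatment stays open. Treatment as the cause predicted a lower share in both CDDO-Im libraries than in both vehicle libraries. That was met, with 16.3% and 60.8% against 70.3% and 82.5%. A share also falls when peaks are added elsewhere. Outside dense megabases the CDDO-Im libraries listed 3249 and 4795 peaks, against 1216 and 1276 for vehicle. The lower share thus cannot tell a change in dense megabases from the gain outside them. By number CDDO-Im 2 went the other way, with 7449 such peaks, more than any other library, but its list was also the longest. In the 203 dense regions of all 4 libraries, the local background of CDDO-Im 1 was 0.94 of the mean of the others, and its tags were 0.978 of the lowest other library and 0.796 of the mean. A higher control background and fewer tags both stay open, because these are only 203 of 11945 dense regions, those that CDDO-Im 1 did list.

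CDDO-Im 2 listed more regions than CDDO-Im 1 outside dense megabases. Thinning its tags to the background of CDDO-Im 1 left 1.45 times as many regions, from 1.47 times, but at the weakest listed −log10 p this moved little. With a −log10 p of at least 8.23 in all lists, the ratio was 1.56 before and 1.42 after thinning. The background also scales with fragment length, and over the shortest peak width CDDO-Im 2 was 1.29 times as deep, which left ratios of 1.40 and 1.23. Depth thus stays open, and no biological explanation was tested, since both libraries have the same treatment. A batch of same-numbered libraries was not tested either and stays open.

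Regions outside dense megabases were gained with CDDO-Im and hardly lost. Thinning both CDDO-Im libraries to the lower vehicle depth left 1421.7 gained regions against 4.1 lost by the background, from 1428 and 4. By the background over peak width with the stricter threshold it left 1152.6 against 4, from 1326 and 2. Depth as the cause predicted no more than 2 times as many gained as lost regions after thinning. The counts argue against depth as the whole cause by these measures. Thinning removes CDDO-Im peaks only and cannot show vehicle peaks that more depth would have added. With dense megabases included, vehicle 2 with CDDO-Im 2 alone held 1841 regions, against 1475 for the CDDO-Im pair. Outside them, the other pairs of libraries held at most 42 such regions against 1428. Among the 1216 top peaks of each library there, they held at most 30 against 359. The latter cut keeps all of vehicle 1 but only the strongest CDDO-Im peaks, so it does not separate the gain from list length. The comparison of pairs restates the pattern. It does not tell CDDO-Im treatment from other differences between the groups, such as the yield of the immunoprecipitation, and 2 libraries against 2 make only 3 splits.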
